A study of Mus musculus with 24 samples.

How the data were processed

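Gene expression was measured with Illumina bead arrays in glial progenitor cells (GPCs) derived from mouse embryonic stem cells. The cells carried a conditional allele of Dgcr8 opposite a deleted allele (flox/delta), and Dgcr8 encodes a component of the microprocessor, the nuclear complex that cuts primary microRNA transcripts. Per the labels, cells were grown in N2 medium with EGF and FGF, and differentiation was started by taking these growth factors away and adding B27 and 1% fetal bovine serum. Per the labels, knockout cells were obtained by 16 h in 1 uM tamoxifen, the drug that induces the deletion, followed by 16 h in 100 nM, and RNA was extracted with Trizol and labelled with biotin. The 24 sample entries describe 19 arrays, because 5 arrays were entered again for a 2nd comparison. The groups were undifferentiated flox/delta cells (3 arrays), differentiated flox/delta cells (3), undifferentiated knockout cells of hybridization 1 (3), and knockout cells of hybridizations 2 and 3 given a mock treatment (4), let-7 (3) or miR-125 (3). The labels also call the 3 knockout arrays of hybridization 1 mock. They list tamoxifen as a treatment for knockout arrays only, and neither tamoxifen nor mock for the flox/delta arrays. The labels give a hybridization number: 9 arrays were in hybridization 1, 2 in hybridization 2 and 8 in hybridization 3. Groups, replicate numbers and hybridizations were taken from the labels alone.

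Per the file headers, the non-normalized table gives a signal intensity and a detection p-value for each of 25697 probes on each array, and its values show no background subtraction. The deposited normalized tables are 4, 1 per comparison. Per the file headers they hold normalized signal, and their values show linear intensity, quantile normalized among 6 arrays, for the differentiation and knockout comparisons. The deposited let-7 and miR-125 tables hold quantile normalized log2 signal, as far as the values show. The deposited series matrix repeats these values, on the intensity scale in 12 columns and on the log2 scale in the other 12. Limma is named in the submitters' processing notes without a version or a role. The normalized tables number the undifferentiated flox/delta and the knockout replicates 1 and 3 the other way round from the non-normalized table, and the numbers of the non-normalized table were used. A symbol was given for 23978 probes and none for 1719, and 23962 of the Entrez gene IDs were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only.

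All tests started from the non-normalized signals of exactly the arrays compared. These were background corrected, quantile normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16. A probe was kept when its detection p was under 0.05 on at least 3 of the arrays, and each gene was represented by its kept probe with the highest mean. Between 12356 and 13617 probes were kept per comparison, giving 9129 to 9935 genes, unnamed probes included. Differences were tested with limma (linear model and empirical Bayes moderation, two-sided), with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of adjusted p under 0.05. The let-7 comparison set 3 let-7 arrays against mock replicate 1 of hybridization 2 and mock replicates 2 and 3 of hybridization 3. It carried a term for the hybridization and left out mock replicate 1 of hybridization 3. The miR-125 comparison lay within hybridization 3. A direct contrast of let-7 with miR-125 used the 10 arrays of hybridizations 2 and 3 with the hybridization term. Fits of these 10 arrays count both mock arrays of replicate 1 as separate samples, although they may hold the same RNA. Where a gene passed and its probe was not above background in 1 group, the fold of that probe was computed against the background level and is given as a lower bound. The text says where another probe of the gene was above background in that group. It also gives the other kept probes of a gene named by the rule where they lay more than 1 log2 unit away, a limit set after the data were seen. Values are means ± SD over arrays, and log2 differences are given ± SE. The p-values measure the spread between these samples. Per the labels, the replicates of the mock, let-7 and miR-125 groups are separate tamoxifen treatments, while the origin of the hybridization 1 replicates is not stated.

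26 lists of genes (cell types, cell cycle, signalling and stress pathways, metabolism, microRNA biogenesis, imprinted genes and known targets of let-7 and miR-125) were tested against all other genes with camera, the competitive set test of limma, at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The test with an estimated correlation has only the residual degrees of freedom of the fit (3 to 6). Its p-values can thus rise without larger correlations between genes. A list was tested when at least 3 members were measured, a minimum set after the data were seen. List p-values were adjusted over the lists of a comparison. Genes higher or lower in the knockout, and in differentiated cells, were tested as sets in the let-7 and miR-125 comparisons. Groups, comparisons, tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names Dgcr8 in the knockout comparison, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, members of each list from the up to 4 with the smallest adjusted p, and a short set of astrocyte, progenitor and let-7 target genes whatever their result. Not every list member that the rule picked is named. For let-7, 3 differences of 1 sign between arrays of the same number replaced the condition on overlap. A gene named outside the rule is said to be so. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.

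Whether arrays of the same number belong together was checked by correlating, across probes, their deviations from the group means. In the let-7 comparison the correlations were 0.87, 0.64 and 0.64 for replicates 1 to 3, and in the miR-125 comparison they were 0.58, 0.39 and 0.46, with each array closest to its own number. These replicates were therefore treated as paired in an alternative with the replicate as a block. Part of the let-7 values comes from the hybridization, since within hybridization 3 the difference between replicates 2 and 3 correlated at 0.347 (0.353 for miR-125). Genes are not independent replicates in these correlations.

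The fits were tested on simulated data with 200 changed genes in each of 5 runs per comparison. At a 2-fold change, 87.8% of the changed genes were recovered in the differentiation comparison, 87.5% in the knockout comparison, 57.0% for let-7, 59.7% for miR-125 and 52.8% in the direct contrast. At a 1.5-fold change these shares were 55.5%, 54.9%, 16.1%, 11.9% and 20.6%. Wrong calls made up 5.62%, 6.39%, 6.88%, 3.47% and 5.21% of the calls. The simulated noise was drawn independently for each gene and array. It held no correlation between genes, no pairing and no hybridization effect, so the shares may differ for the real arrays.

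Alternatives were quantile normalization without background correction, normexp with median scaling (offset of 50), the deposited normalized values, no detection filter, a detection p of 0.01, every probe tested on its own, a fold minimum of 1.5, all arrays of the same hybridizations, the replicate as a block, hybridization 3 alone, no hybridization term, and leaving out each array in turn. Added after the data were seen were a variance prior that follows intensity, this prior and quantile normalization without background correction each combined with the block, neqc offsets of 50 and 100, leaving out each array in the list tests, the cell cycle list without background correction, the 200 largest changes per set with an estimated correlation, the lists in the direct contrast, and the block with the numbering of the normalized tables. Hybridization 2 holds a single pair of mock and let-7 arrays. In fits with the hybridization term, leaving out either array of this pair removes what the other adds. These leave-out runs are therefore not separate checks. Every comparison of 3 against 3 arrays was also repeated for the 10 ways to split its arrays. Sets of genes with let-7 or miR-125 seed sites were not analysed here, since that needs 3' UTR sequences. The number of arrays limits the precision of all values.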

Results

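The series compared glial progenitor cells before and after differentiation, with and without Dgcr8, and after let-7 or miR-125 had been given back to knockout cells. As its title frames it, the question was whether these 2 microRNAs act together in the formation of astrocytes. Expression was measured on 19 arrays: 3 of undifferentiated and 3 of differentiated flox/delta GPCs, 3 of undifferentiated knockout GPCs that the labels also call mock, 4 of mock-treated knockout GPCs for the microRNA comparisons, and 3 each of knockout GPCs with let-7 or miR-125. Mean raw signal ranged from 298 to 474 in hybridization 1, from 1429 to 1523 in hybridization 2 and from 756 to 868 in hybridization 3. Between 11788 and 13129 of the 25697 probes were detected per array. The signal of detected probes was 2.22 to 3.15 times the background in hybridization 1, 5.89 to 5.99 times in hybridization 2 and 3.18 to 3.44 times in hybridization 3, and levels were compared only among arrays normalized together.

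The comparison of differentiated with undifferentiated flox/delta cells asked what changes when growth factors are replaced by serum, and genes of astrocytes rose. Gfap, the intermediate filament protein of astrocytes, was at background in the undifferentiated cells (log2 signal 4.37 ± 0.07, SD, n = 3) and reached 11.12 ± 0.04 (n = 3) in the differentiated cells, at least 83.0-fold higher (adjusted p = 4.96e-10). Aqp4, the water channel of astrocytes, rose by 6.30 ± 0.27 on the log2 scale (12.07 ± 0.47 against 5.77 ± 0.47, n = 3 each, adjusted p = 1.24e-07). Clu, which encodes the secreted chaperone clusterin, rose by 6.21 ± 0.20 (adjusted p = 2.64e-08), and the zinc transporter gene Slc39a12 by 4.93 ± 0.10 (adjusted p = 4.28e-09). Of 24 measured astrocyte markers 19 rose, with a median log2 difference of 1.10 over the list, and 2 fell (camera adjusted p = 1.47e-06, and adjusted p = 0.335 with an estimated correlation). The members that fell, Acsbg1 (-1.62 ± 0.11) and Cbs (-0.36 ± 0.13), were picked out after their values were seen. S100b, a calcium-binding protein of astrocytes, did not pass (0.34 ± 0.18, adjusted p = 0.128) and was detected on only 2 differentiated arrays and 1 undifferentiated array.

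Genes of other neural lineages rose too. Of 14 oligodendrocyte lineage markers 11 rose and 1 fell (median 1.30, adjusted p = 0.000682, and adjusted p = 0.335 with an estimated correlation). Among them were Gpr17, a receptor of early oligodendrocytes (5.20 ± 0.20), Lims2 (5.28 ± 0.18), the myelin gene Mbp (4.80 ± 0.21, and 1.20 on its other probe) and Ugt8a (2.47 ± 0.12), a synthase of myelin lipids. Opalin, the member that fell (-1.38 ± 0.19), was picked out after its value was seen. Of 16 neuron markers 8 rose and 2 fell (median 0.70, adjusted p = 0.0293, and adjusted p = 0.235 with an estimated correlation). Dcx, a microtubule protein of young neurons, rose by 3.43 ± 0.10, Uchl1 by 1.88 ± 0.10 and the neuronal splicing factor gene Rbfox3 by 1.88 ± 0.15, and Elavl3 was at least 3.43-fold higher. This list did not pass without differentiated replicate 2 (adjusted p = 0.0510), and Tubb3 was not kept. Neural progenitor markers went both ways, with 4 of 18 higher and 8 lower: Sox9, a transcription factor of glia and their progenitors, rose by 1.11 ± 0.12 and Vim by 0.56 ± 0.09, while Nes, which encodes the filament protein nestin, fell by 0.70 ± 0.11 and the growth factor receptor gene Egfr fell by 1.43 ± 0.09.

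The genes of cell division fell almost without exception. Of 42 measured cell cycle genes 40 fell and 2 rose (median -3.25, or -3.22 with members not above background at their bound; adjusted p = 4.49e-22, and adjusted p = 0.0883 with an estimated correlation). Cdk1, the kinase that drives mitosis, fell by 4.75 ± 0.11 (-0.71 on its other probe), and Top2a, the topoisomerase of dividing cells, by 4.62 ± 0.11. The centromeric histone gene Cenpa fell by 4.68 ± 0.09 and Cdc20 fell by 4.67 ± 0.10 (-4.51 to -3.54 on other probes). The members that rose, named after their values were seen, were Ccnd3 (0.70 ± 0.12) and E2f5 (0.39 ± 0.14). Among the largest falls of all genes were also Fbln2, an extracellular matrix gene (-6.57 ± 0.10, adjusted p = 6.22e-10, and -3.35 on its other probe), Tk1, the thymidine kinase of DNA synthesis (-6.10 ± 0.09, and -2.76 on its other probe), and Igfbp4, which encodes a binding protein of insulin-like growth factors (-5.64 ± 0.15). Dcpp1 (-5.41), Pbk (-5.03), Pclaf (-4.88) and Cdca3 (-4.81) followed. The largest rises besides those above were those of Glycam1 (at least 158-fold), Gbp2 (at least 50.5-fold, with a log2 difference of 1.61 on its other probe), Ly6h (6.13, and 4.71 to 6.33 on other probes), Hspb8 (5.34 ± 0.09), Ahnak (5.30) and Psd2 (5.28).

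**Figure D1:**
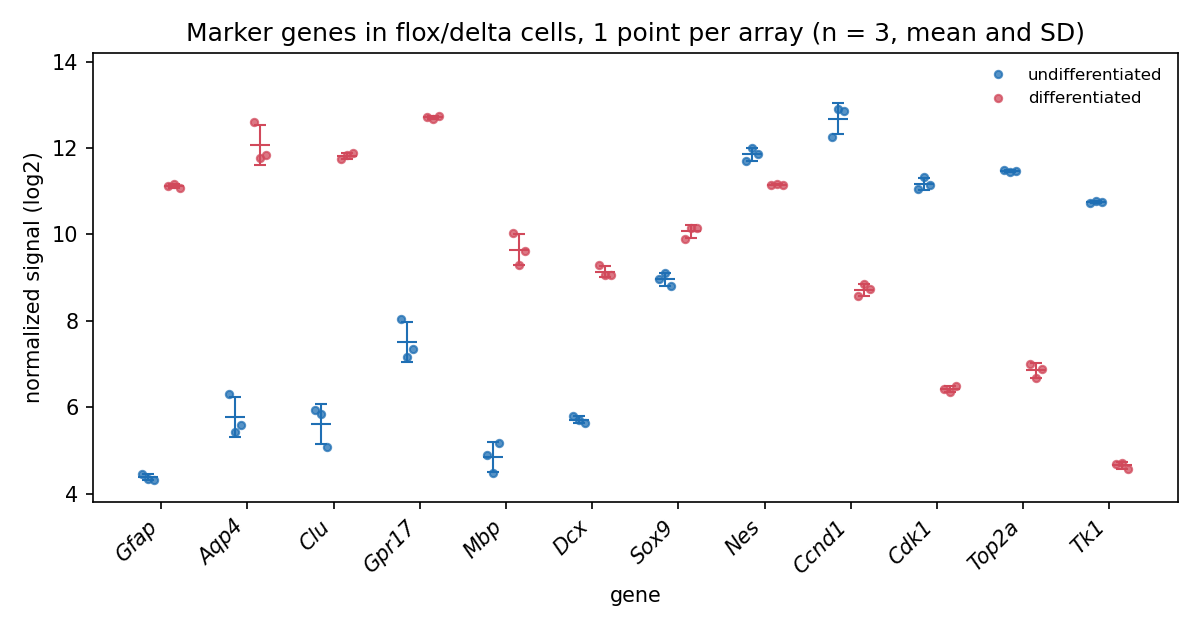
Normalized log2 signal (y axis) of 12 genes (x axis) in undifferentiated (blue) and differentiated (red) flox/delta GPCs, where points are arrays (n = 3 per group) and lines give the mean and SD. Gfap went from 4.37 to 11.12 and Aqp4 from 5.77 to 12.07, while Cdk1 went from 11.17 to 6.42.

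Signalling, stress and metabolic genes also moved with differentiation. All 6 genes that passed among 7 inflammatory and NF-kB genes rose (median 0.95, or 0.63 with members at their bound, adjusted p = 0.00757, and adjusted p = 0.227 with an estimated correlation), among them Vcam1 (2.80 ± 0.12) and Lcn2 (at least 6.36-fold). This list did not pass without differentiated replicate 2 (adjusted p = 0.0510). Of 18 p53 target genes 12 fell, including Plk2 (-2.94 ± 0.17) and Cdkn1a (-1.64 ± 0.09), while Fas, the death receptor, rose by 3.81 ± 0.10 (median -0.56, adjusted p = 0.00965, and adjusted p = 0.227 with an estimated correlation). Of 19 hypoxia and glycolysis genes 11 fell, such as Vegfa (-2.43 ± 0.12) and Ldha (-1.37 ± 0.09), and 3 rose (median -0.47, adjusted p = 0.0179, and adjusted p = 0.444 with an estimated correlation). Among these, Pfkp was at least 12.4-fold higher on 1 probe and at 1.79 on the other kept probe, and a probe of it was above background on 1 undifferentiated array. Of 27 ribosomal protein genes 13 fell, with Rplp0 at -1.20 and Rpl4 at -1.18 (median -0.25, adjusted p = 0.00861, and adjusted p = 0.227 with an estimated correlation). Of 24 known let-7 targets 14 fell, led by Rrm2 (-3.84 ± 0.12), Ccnd1 (-3.96 ± 0.17) and Dusp6 (-3.98 ± 0.17, and -2.89 to -1.83 on other probes), and 6 rose (median -0.37, adjusted p = 0.0389, and adjusted p = 0.361 with an estimated correlation). That list did not pass without differentiated replicate 2 (adjusted p = 0.0579) or replicate 3 (adjusted p = 0.0871). Rrm2 and Ccnd1 are also on the cell cycle list, and known let-7 targets were not tested without such members.

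The other 14 lists did not pass in differentiation (adjusted p = 0.135 to 0.759), although members of each did. Etv5 (-4.25) and Etv4 (-3.64), factors induced by growth factor signalling, fell among 16 immediate early genes (4 rose, 7 fell), while Fos rose by 3.65. In the JAK-STAT, LIF and BMP list 9 of 19 rose, with Socs3 at 3.39 ± 0.11, Id4 at 3.04 and Il6st at 2.17, and 5 fell, with Bmp7 at -2.40. In the Notch list 9 of 21 rose and 6 fell (Hey1 1.35, Hes6 -1.51). Cell cycle inhibitors had 2 rises in 11, among them Cdkn2b (1.97 ± 0.13), and 5 falls, such as Rbl1 (-2.39) and Cdkn2c (-2.04, and 0.08 on its other probe). Known miR-125 targets had 6 rises and 13 falls in 30 (adjusted p = 0.135), such as Bmf (1.72) and Ets1 (-1.81). In the amino acid and unfolded protein response list 9 of 24 rose, with Slc7a11 at 2.83, and 8 fell, with Mthfd2 at -2.25. Rises and falls numbered 3 and 9 in 18 cholesterol biosynthesis genes (Ebp -1.13), 6 and 4 in 14 interferon response genes (Ifi27 1.52, Irf9 1.32), 3 and 2 in 14 microRNA biogenesis genes (Tarbp2 -0.96, Xpo5 0.46) and 2 and 4 in 11 imprinted genes (Mest -2.29, Nnat 1.78). They numbered 0 and 2 in 7 pluripotency markers (Esrrb -1.71, Klf4 -1.47), 3 and 3 in 6 mesenchymal and smooth muscle markers (Thy1 -1.79, Col5a1 1.04) and 1 and 0 in 4 endoderm and mesoderm markers (Cxcr4 3.15 ± 0.16). The interferon median was 0.16, or 0.02 with members at their bound. Median, mean and test differed in sign for the mesenchymal list (0.00, -0.82, down) and the amino acid list (-0.05, 0.12, up). Microglia, endothelial and primary microRNA host lists had 0, 1 and 1 measured members and were not tested; Egfl7 (-0.61) and Mcm7 (-3.06) fell. Adjusted over the list alone, counts were as above except for neurons (10 higher, 2 lower), p53 targets (1, 14), known let-7 targets (7, 14), neural progenitors (4, 9), JAK-STAT genes (10, 5) and Notch genes (9, 8).

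In all, 5193 of 9404 genes passed in differentiation (limma, 3 arrays against 3), 2631 higher and 2562 lower, and 3109 of them differed by at least 1.5-fold. The 2 groups did not overlap for 5871 genes (62.4%, where chance gives 10%). With normexp and median scaling 2635 genes passed.

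The comparison of knockout with flox/delta progenitors addressed loss of Dgcr8, and with it of most microRNAs, before differentiation. The labels name tamoxifen and mock for the knockout arrays and neither for the flox/delta arrays, so the differences below were not separated from effects of these treatments. Dgcr8 itself fell by 0.52 ± 0.12 (6.84 ± 0.19 against 7.36 ± 0.12, n = 3 each, adjusted p = 0.00495), with no overlap between groups. Where its only probe lies relative to the deleted part is unknown, so this value checks nothing about the knockout. Igdcc3, a cell surface protein gene of the immunoglobulin superfamily, rose by 6.08 ± 0.13 (adjusted p = 1.52e-08), and Tgfbr2, a receptor of TGF-beta, by 5.13 ± 0.15 (12.57 ± 0.02 against 7.44 ± 0.31, adjusted p = 2.94e-08, and 2.78 on its other probe). Calb2, the calcium-binding protein calretinin, rose by 5.06 ± 0.12 (3.96 on its other probe). Ncan, a proteoglycan of the brain matrix, fell by 5.63 ± 0.18 (5.81 ± 0.35 against 11.44 ± 0.20, adjusted p = 5.08e-08), Ntrk2, the receptor of BDNF, fell by 5.38 ± 0.14 (-0.75 on its other probe) and Hes5, an effector of Notch, fell by 5.33 ± 0.20.

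Known targets of let-7 rose together in the knockout. Of 26 measured, 22 rose and 2 fell (median 1.19, adjusted p = 1.36e-06, and adjusted p = 0.201 with an estimated correlation). Arid3b was at least 5.32-fold higher, and the transcription factor genes Plagl2, Nr6a1 and Arid3a rose by 2.39 ± 0.09, 1.78 ± 0.11 and 1.38 ± 0.12. The receptor gene Tgfbr1 rose by 1.93 ± 0.09 and Fign by 1.60 ± 0.09. The members that fell were Nr2e1 (-1.24 ± 0.12) and Map4k4 (-0.81 ± 0.16), named after their values were seen. Hmga2 and Lin28a, with 2 probes each, were not kept, and Igf2bp2 and Lin28b had no named probe. Known miR-125 targets went both ways, with 13 of 31 higher, 8 lower and adjusted p = 0.274; Arid3b and Arid3a are on this list as well, Plk3 rose by 1.90 ± 0.15 and Lifr was at least 1.90-fold lower.

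**Figure D2:**
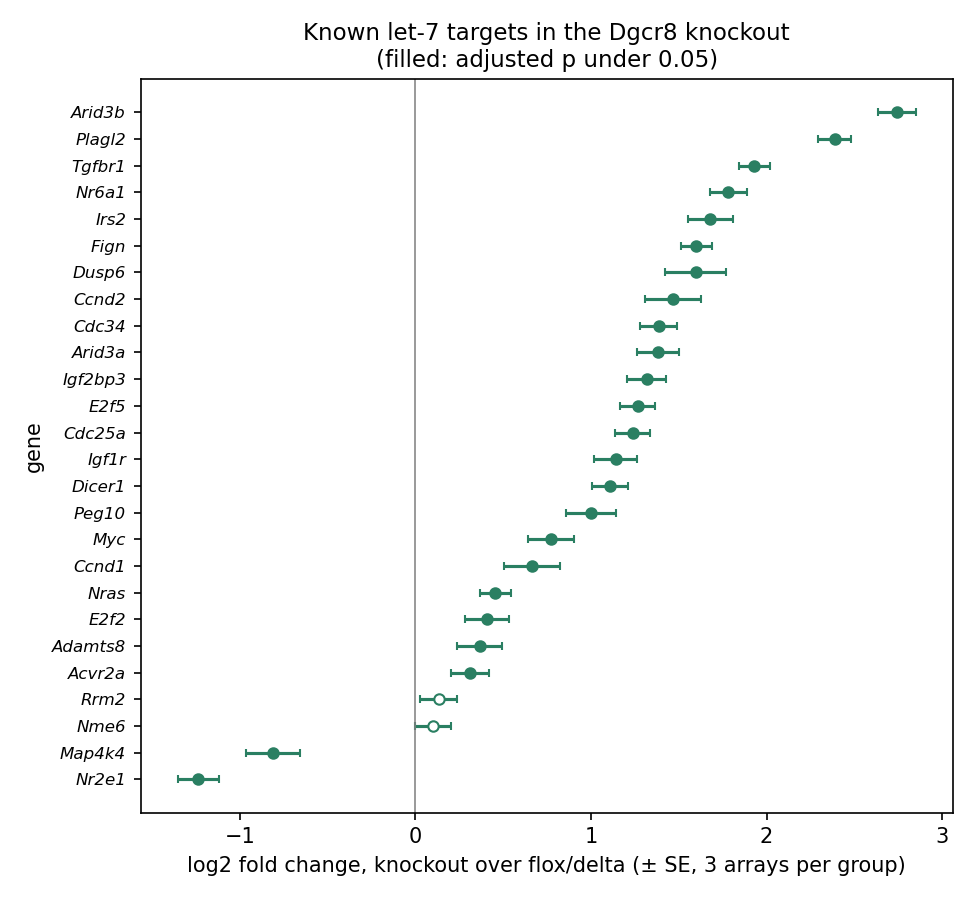
Log2 fold change (x axis) of 26 known let-7 targets (y axis) in knockout over flox/delta GPCs, 3 arrays each, where points are fitted values, bars give the SE and filled points passed at adjusted p under 0.05. The 22 that rose include Plagl2 at 2.39, Map4k4 and Nr2e1 fell, and Rrm2 and Nme6 did not pass.

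Markers of glia were lower in the knockout before any differentiation. All 10 measured oligodendrocyte lineage markers fell (median -1.87, adjusted p = 1.28e-05, and adjusted p = 0.201 with an estimated correlation), such as Bcas1 (-3.17 ± 0.10), while Gpr17 was at least 7.04-fold, Cldn11 at least 5.65-fold and Opalin at least 4.30-fold lower. Of 20 astrocyte markers 13 fell and 3 rose (median -0.76, or -0.65 at the bounds, adjusted p = 0.00205, and adjusted p = 0.430 with an estimated correlation). Ttyh1 fell by 4.47 ± 0.14 (-2.57 on its other probe) and the lipid carrier gene Apoe by 4.26 ± 0.21. Fgfr3 fell by 3.18 ± 0.16 (-0.82 on its other probe) and Gpr37l1 was at least 3.70-fold lower. Htra1 (0.69 ± 0.11), Aldh1l1 (1.15 ± 0.18) and Cbs (0.62 ± 0.12) rose and, like Aqp4, were looked up after the data were seen; Aqp4 did not pass (0.07, adjusted p = 0.805). Of 16 neuron markers 9 fell and 3 rose (median -0.58, or -0.46 at the bounds, adjusted p = 0.0253, and adjusted p = 0.212 with an estimated correlation), with Nsg2 at least 10.5-fold lower, the synaptic vesicle gene Syp at -2.34 ± 0.11, Ncam1 at -2.28 ± 0.13 (0.01 on its other probe) and Uchl1 at 1.59 ± 0.10. Without flox/delta replicate 1, 2 or 3 the neuron list did not pass (adjusted p = 0.221, 0.255 and 0.226). Of 20 neural progenitor markers 10 fell, including Sox9 (-2.06 ± 0.11) and the Notch ligand gene Dll1 (-2.11 ± 0.11), 4 rose, with Cd24a at least 1.93-fold higher, and the list missed the threshold (adjusted p = 0.0608). With an estimated correlation it had adjusted p = 0.252. It passed with the replicate as a block (adjusted p = 0.0455, and adjusted p = 0.495 with an estimated correlation) and, at the preset correlation, without any 1 array, at adjusted p = 0.0454, 0.0472 and 0.0385 without flox/delta replicates 1, 2 and 3 and adjusted p = 0.0216, 0.0195 and 0.0280 without knockout replicates 1, 2 and 3.

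The lists of microRNA biogenesis, of amino acid and unfolded protein response and of cell cycle genes passed upward in the knockout. Of 14 microRNA biogenesis genes 10 rose and Dgcr8 alone fell (median 0.43, adjusted p = 0.0120, and adjusted p = 0.212 with an estimated correlation). Tnrc6c and Tnrc6a, partners of Argonaute, rose by 1.46 ± 0.11 and 1.30 ± 0.09, the Argonaute gene Ago2 by 1.41 ± 0.13 and Dicer1, which processes precursor microRNAs, by 1.11 ± 0.10. Of 25 amino acid and unfolded protein response genes 13 rose, among them Chac1 (2.46 ± 0.11), Slc7a3 (1.32) and Mthfd2 (1.22), and 2 fell, Ddit4 (-1.14) and, as seen afterwards, Slc7a11 (median 0.36, adjusted p = 0.0231, and adjusted p = 0.212 with an estimated correlation). Of 42 cell cycle genes 18 rose and 3 fell (median 0.20, adjusted p = 0.0169, and adjusted p = 0.352 with an estimated correlation). This list holds known let-7 and miR-125 targets, and it was not tested without them in the knockout. E2f1, a transcription factor of S phase entry, rose by 2.05 ± 0.13, E2f5 by 1.27 ± 0.10, Cdc25a by 1.24 ± 0.10 and Ccne1 by 1.23 ± 0.12.

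The other 16 lists did not pass in the knockout (adjusted p = 0.0608 to 0.968). The Notch list had 8 rises and 8 falls in 19 (Nrarp -2.09), the JAK-STAT, LIF and BMP list 6 and 9 in 21 (Socs3 1.75, Id1 -1.22), immediate early genes 7 and 4 in 15 (Dusp1 2.09, Fos -2.02, Dusp6 1.60, Spred1 0.94) and cell cycle inhibitors 2 and 6 in 10 (Cdkn2c -1.69, Cdkn2d -0.91, Cdkn1a -0.68, Btg1 0.67). Hypoxia and glycolysis genes had 4 and 7 in 20 (Slc2a3 -2.67, Vegfa -1.38) and passed without knockout replicate 3 (adjusted p = 0.0333). Imprinted genes had 7 and 3 in 12 (Igf2r 2.05, Snrpn -1.42, Ndn 0.88) and passed without flox/delta replicate 1 (adjusted p = 0.0322) or replicate 2 (adjusted p = 0.0472). Interferon genes had 5 and 2 in 12 (Ifi27 -1.43, Rsad2 1.14; median 0.33, or 0.20 at the bounds), p53 targets 6 and 4 in 17 (Sesn1 -1.17), inflammatory and NF-kB genes 1 and 3 in 6 (Vcam1 -1.98), cholesterol genes 3 and 4 in 18 (Hsd17b7 1.20, Pmvk -0.93) and ribosomal protein genes 0 and 3 in 27 (Rpl22 -0.67). Markers of other cell types had 1 rise and 1 fall in 7 pluripotency markers (Klf2 1.51, Klf4 at least 3.66-fold lower), 2 and 2 in 7 mesenchymal and smooth muscle markers (Dcn at least 10.8-fold higher with 2.00 on its other probe, Col5a1 1.73, Fbln2 -1.11, Thy1 at least 4.86-fold lower) and 1 and 0 in 4 endoderm and mesoderm markers (Cxcr4 1.19). Microglia, endothelial and primary microRNA host lists had 0, 2 and 1 measured members and were not tested; Tek was at least 1.43-fold higher (endothelial median 0.39, or 0.25 at the bounds) and Mcm7 rose by 0.60. Median, mean and test differed in sign for the JAK-STAT (0.06, -0.06, down), Notch (0.09, -0.56, down) and p53 lists (0.01, 0.01, down). Adjusted over the list alone, counts were as above except for neural progenitors (5 higher, 11 lower), Notch (8, 9), cholesterol (2, 4), hypoxia (4, 9), known miR-125 targets (14, 8) and ribosomal proteins (0, 1).

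In all, 5005 of 9129 genes passed in the knockout (limma), 2579 higher and 2426 lower, 2723 of them by at least 1.5-fold, and the groups did not overlap for 5690 (62.3%, where chance gives 10%). With normexp and median scaling 1397 genes passed, 776 higher and 621 lower. The largest rises also included Sel1l3 (4.67 ± 0.18), Anxa5 (4.53 ± 0.11), Thbs2 (4.16), Glipr2 (3.95, and 1.55 on its other probe), Gbx2 (3.88), Tnnt1 (at least 15.4-fold) and Rgs16 (at least 15-fold). The largest falls also included Kcnip3 (-5.01), Brinp2 (-4.89), Myt1 (-4.78), Plxnb3 (-4.57), Mmd2 (at least 38.0-fold) and Scrg1 (at least 22.3-fold). Draxin was lower by at least 27.9-fold on 1 probe only, with other probes at -1.08 and -0.23 and above background on 2 knockout arrays.

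Giving let-7 to knockout cells addressed what this microRNA alone moves. Cdkn2b, an inhibitor of the cyclin D kinases, rose by 1.93 ± 0.13 over mock (adjusted p = 0.0369; 2.08, 2.02 and 1.68 in replicates 1 to 3, n = 3). Ramp2, which encodes a receptor accessory protein, rose by 1.56 ± 0.11 (adjusted p = 0.0369; 1.58, 1.65 and 1.44). Both genes were lower in knockout than in flox/delta cells (Cdkn2b -0.52, Ramp2 -2.67), values looked up afterwards. Known let-7 targets were lower as a group, 25 of 29 of them, with a median of -0.57 (adjusted p = 2.43e-06, and adjusted p = 0.693 with an estimated correlation; -0.72, -0.49 and -0.28 in replicates 1 to 3). Mock replicate 1 of hybridization 2, the only mock array there, stood apart from the other mock arrays on this list (median log2 signal 9.03 against 9.23 to 9.26). The list passed without any 1 array (adjusted p of at most 6.31e-05). No single target passed over all genes, while 13 were lower adjusted over the list alone, among them Arid3a (-0.97 ± 0.17, adjusted p = 0.135 over all genes), Plagl2 (-0.84 ± 0.19, adjusted p = 0.145), Nr6a1 (-0.82 ± 0.22, adjusted p = 0.165), and, named after their values were seen, Dicer1 (-0.73 ± 0.15) and Tgfbr1 (-0.64 ± 0.12).

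Cell cycle genes were lower after let-7 and interferon response genes higher. Of 42 cell cycle genes 41 were lower (median -0.39, adjusted p = 2.20e-09, and adjusted p = 0.693 with an estimated correlation), by -0.63 in replicate 1 of hybridization 2 and by -0.29 and -0.24 in replicates 2 and 3 of hybridization 3. None of them passed adjusted over the list alone. Of 17 interferon response genes 15 were higher (median 0.38, adjusted p = 0.00237, and adjusted p = 0.693 with an estimated correlation), with Tap1 (0.85 ± 0.17), Ifi27 (0.86 ± 0.18) and Ifitm3 (0.91 ± 0.22) higher adjusted over the list alone and named for that. Mock replicate 2 stood apart from the other mock arrays on this list (median log2 signal 6.93 against 6.27 to 6.32). The interferon list passed without this array (adjusted p = 0.000121) and did not pass without let-7 replicate 2 (adjusted p = 0.0511). The other 19 lists tested did not pass (adjusted p = 0.101 to 0.846), among them known miR-125 targets (median -0.03, adjusted p = 0.272, 3 lower adjusted over the list alone) and astrocyte markers (13 of 21 higher, median 0.12, adjusted p = 0.218). Aqp4, looked up afterwards, was at -0.30 ± 0.29 (adjusted p = 0.622), and Gfap was not kept. Immediate early genes and microRNA biogenesis genes each passed without mock replicate 3 (adjusted p = 0.0354). Adjusted over the list alone, higher and lower members numbered 3 and 1 for neurons, 0 and 2 for oligodendrocytes, 1 and 0 for pluripotency, 2 and 1 for mesenchyme, 3 and 1 for cell cycle inhibitors, 1 and 1 for immediate early genes, and 0 and 1 each for microRNA biogenesis and primary hosts. Median, mean and test differed in sign for cell cycle inhibitors (-0.04, 0.30, up), JAK-STAT (-0.05, 0.04, up), p53 (-0.02, 0.02, up) and amino acid response genes (-0.03, 0.04, up). Microglia, endothelial, endoderm and primary host lists had 1, 2, 2 and 1 measured members and were not tested.

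Of 9433 genes, 2 passed after let-7 (limma), while 1724 had an unadjusted p under 0.05 where chance gives 472, and groups did not overlap for 1223 (13%). Chance gives 10% for exchangeable arrays, which these were not, since same-numbered arrays went together. No valid chance share was therefore at hand for this count or for those of miR-125 and the direct contrast. With the replicate as a block 6 passed, with quantile normalization without background correction 251 (148 higher, 103 lower), with median scaling 106 (99 higher, 7 lower) and with a variance prior that follows intensity 303 (179 higher, 124 lower). No gene passed without mock replicate 1, 2 or 3 or without let-7 replicate 1, 2 or 3, with no detection filter, with no hybridization term or within hybridization 3 alone.

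After miR-125, the known targets of this microRNA were lower as a group. Of 30 measured, 28 were lower (median -0.49, adjusted p = 3.54e-09, and adjusted p = 0.947 with an estimated correlation; -0.66, -0.53 and -0.38 in replicates 1 to 3, n = 3). Trp53inp1, a p53-induced gene, was at -1.03 ± 0.14 (adjusted p = 0.0982), Mknk2 at -0.77 ± 0.14 (adjusted p = 0.101), the sialidase gene Neu1 at -0.78 ± 0.15 (adjusted p = 0.102), Bap1 at -0.81 ± 0.18 (adjusted p = 0.110) and Arid3a at -1.45 ± 0.34 (adjusted p = 0.111). These are among 13 members lower adjusted over the list alone and, but for Arid3a, were named after their values were seen. Cell cycle genes were lower as well, 40 of 42 of them (median -0.46, adjusted p = 5.38e-09, and adjusted p = 0.963 with an estimated correlation; -0.70, -0.39 and -0.29 in replicates 1 to 3), with none past adjusted over the list alone.

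The other 21 lists tested did not pass after miR-125 (adjusted p = 0.376 to 0.972). Known let-7 targets had a median of -0.19 (adjusted p = 0.376, 3 higher and 4 lower adjusted over the list alone), with Nr6a1 at -0.79 ± 0.25 (adjusted p = 0.154) and Plagl2 at -0.39 ± 0.13 (adjusted p = 0.170). Interferon response genes had a median of 0.03 and a mean of -0.04 with the test upward (adjusted p = 0.972). Astrocyte markers were higher in 7 of 18 (median -0.11, adjusted p = 0.921), with Aqp4 at -0.24 ± 0.41 (adjusted p = 0.800), looked up afterwards. Amino acid response genes passed without mock replicate 2 (adjusted p = 0.0400), and immediate early genes and p53 targets each passed without miR-125 replicate 1 (adjusted p = 0.0186). Median, mean and test also differed in sign for neural progenitors (-0.12, -0.06, up) and JAK-STAT genes (0.02, -0.00, down). Adjusted over the list alone, higher and lower members numbered 2 and 0 each for neurons, JAK-STAT, NF-kB and immediate early genes, 2 and 2 for oligodendrocytes, 2 and 1 for p53 targets, 1 and 0 each for cell cycle inhibitors and hypoxia, and 0 and 1 for interferon. Microglia, endothelial and primary host lists had 1, 2 and 1 measured members and were not tested.

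Of 9326 genes, 0 passed after miR-125 (limma), while 1842 had an unadjusted p under 0.05 where chance gives 466, and groups did not overlap for 2450 (26.3%, where chance gives 10% for exchangeable arrays). With the replicate as a block 3 passed, with quantile normalization without background correction 187 (108 higher, 79 lower), with median scaling 44 (40 higher, 4 lower), with all 10 arrays of hybridizations 2 and 3 350 (195 higher, 155 lower) and with a variance prior that follows intensity 235 (139 higher, 96 lower). The fit of all 10 arrays counts both mock arrays of replicate 1 as separate samples, although they may hold the same RNA.

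**Figure D3:**
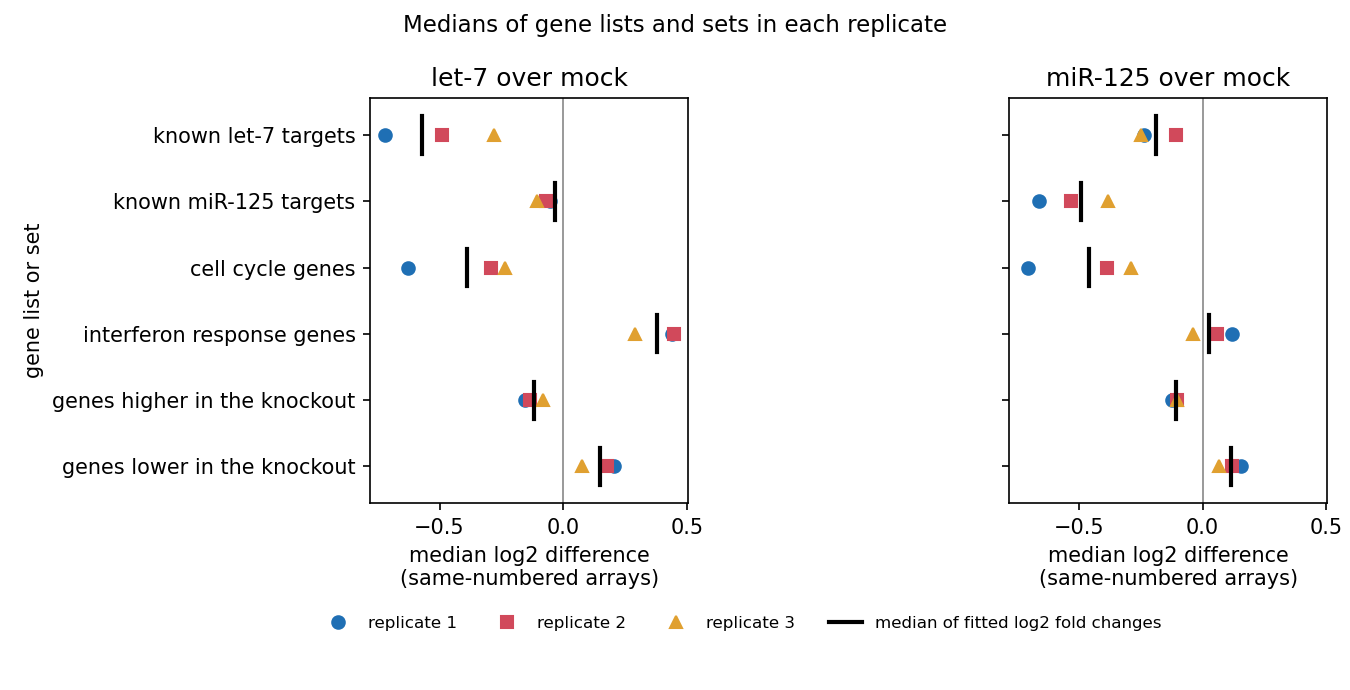
Median log2 difference (x axis) of 6 gene lists and sets (y axis) between same-numbered arrays of let-7 and mock (left) and of miR-125 and mock (right), where points are replicates 1 to 3 and black lines give the median of the fitted log2 fold changes. Known let-7 targets lie at -0.57 after let-7 and -0.19 after miR-125, known miR-125 targets at -0.03 and -0.49.

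The direct contrast of let-7 with miR-125 tested where the microRNAs differ. Known miR-125 targets were higher with let-7 than with miR-125 in 25 of 30 (median 0.40, adjusted p = 8.15e-05, and adjusted p = 0.956 with an estimated correlation), and Neu1 passed on its own (1.15 ± 0.19, adjusted p = 0.0423). On this list mock replicate 1 of hybridization 2 stood apart (median log2 signal 10.18 against 10.01 to 10.03), and the list passed without it (adjusted p = 5.13e-05) and without any other array (adjusted p of at most 0.00385). Interferon response genes were higher with let-7 in 17 of 18 (median 0.33, adjusted p = 0.0143, and adjusted p = 0.956 with an estimated correlation). That list passed without mock replicate 2, the array that stood apart on it (adjusted p = 0.0115). It did not pass without let-7 replicate 2 (adjusted p = 0.267) or without miR-125 replicate 1 or 3 (adjusted p = 0.0630 and 0.211). Adjusted over the list alone, 10 miR-125 targets were higher and 2 lower, and 0 interferon genes passed. Known let-7 targets were lower with let-7 in 17 of 29 (median -0.09) and did not pass (adjusted p = 0.253); 5 were lower adjusted over the list alone, and Nme6 (-1.45 ± 0.19, adjusted p = 0.0275) and Cdc34 (-1.08 ± 0.19, adjusted p = 0.0445) passed over all genes. Cell cycle genes did not pass (30 of 42 higher, median 0.11, adjusted p = 0.582), and the 21 lists that did not pass had adjusted p = 0.253 to 0.925. Adjusted over the list alone, higher and lower members of these lists numbered 2 and 4 for p53 targets, 1 and 2 each for NF-kB and microRNA biogenesis genes, 1 and 0 each for astrocytes, pluripotency and cell cycle inhibitors, and 0 and 1 each for neurons, oligodendrocytes, mesenchyme and Notch. Median, mean and test differed in sign for NF-kB (0.30, -0.15, down), cholesterol (-0.03, 0.03, down), hypoxia (0.05, 0.00, down), amino acid (-0.02, 0.01, down), imprinted (-0.04, 0.09, up) and ribosomal genes (0.01, -0.02, down). Microglia, endothelial and primary host lists had 2, 2 and 1 measured members and were not tested.

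Single genes that differed most were Actg2, a smooth muscle actin (-2.68 ± 0.31, adjusted p = 0.0275), A3galt2 (-2.34 ± 0.30), Rasl11a (-1.92), Rbfox3 (-1.58), Gmip (-1.35) and Bok (-1.27 ± 0.16), lower with let-7, and Gzmm (at least 2.30-fold), Fgf17 (at least 2.03-fold) and Pygl (at least 1.80-fold) were also lower. Pygl had another kept probe with the opposite sign (0.27), and a probe of it was above background on 1 let-7 array. Its sign turned without miR-125 replicate 2 (0.24) or replicate 3 (0.12). Higher with let-7 were Dusp23 (1.90 ± 0.23, adjusted p = 0.0275), Ociad2 (1.83 ± 0.32), Slc46a3 (1.77), P2rx4 (1.45), Rhebl1 (1.41), Adamts4 (1.40), Vmac (1.40), Aig1 (1.32), Lgals8 (1.29 ± 0.17) and 1 probe of Gcnt2 (at least 2.25-fold), another being above background on 1 miR-125 array. The fit includes the mock arrays through the hybridization term, and 1 of these stood apart for Dusp23 (log2 signal 6.47 on the array of hybridization 2 against 7.16 to 7.28), Slc46a3 (6.73 against 7.34 to 7.43) and Rhebl1 (8.42 against 8.75 to 8.81). In all, 118 of 9935 genes passed (limma, 10 arrays), 50 higher and 68 lower, and groups did not overlap for 1978 (19.9%, where chance gives 10% for exchangeable arrays). This fit counts both mock arrays of replicate 1 as separate samples, and whether they hold the same RNA is not stated. With the replicate as a block 579 passed (319 higher, 260 lower), with quantile normalization without background correction 372 (192, 180), with median scaling 201 (111, 90), with no detection filter 17 (4, 13) and within hybridization 3 alone 0. The count was 0 without mock replicate 1 of hybridization 2, let-7 replicate 1 or 2, or miR-125 replicate 1 or 2, 22 without mock replicate 1 of hybridization 3, 23 and 21 without mock replicates 2 and 3, 15 without let-7 replicate 3 and 76 without miR-125 replicate 3.

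Genes that differed in the knockout went, as sets, the other way after each microRNA. Both microRNAs were compared with mock alone, so effects of giving any small RNA were not separated from these shifts. Of 2560 genes higher in the knockout, 1767 were lower after let-7 (median -0.12, adjusted p = 2.95e-08), and of 2306 genes lower in the knockout, 1641 were higher (median 0.15, adjusted p = 2.67e-12; both adjusted p = 0.148 with an estimated correlation). After miR-125, 1653 of 2549 genes higher in the knockout were lower (median -0.11, adjusted p = 5.05e-05), and 1421 of 2280 genes lower in it were higher (median 0.11, adjusted p = 6.13e-07; both adjusted p = 0.182 with an estimated correlation). The medians had the same sign in replicates 1 to 3: -0.16, -0.13 and -0.08, and 0.20, 0.18 and 0.08 after let-7, and -0.12, -0.10 and -0.10, and 0.16, 0.12 and 0.07 after miR-125. Genes that rise in differentiation were higher after let-7 (2344 genes, median 0.06, adjusted p = 0.00269, and adjusted p = 0.184 with an estimated correlation), and those that fall were lower (2512 genes, median -0.06, adjusted p = 0.0413, and adjusted p = 0.182 with an estimated correlation). Differentiation and knockout sets were both called against the same undifferentiated flox/delta arrays, so their results are not independent of each other. The set of falling genes did not pass without mock replicate 1 of hybridization 2 (adjusted p = 0.136) or let-7 replicate 1 (adjusted p = 0.148). With the hybridization term both of these fits lose the same pair of arrays. The set of falling genes also did not pass without mock replicate 3 (adjusted p = 0.0540) or let-7 replicate 2 (adjusted p = 0.0844). With no detection filter it did not pass either (adjusted p = 0.0547). After miR-125 neither set of differentiation genes passed (medians 0.02 and -0.05, adjusted p = 0.136 and 0.152). Both full sets passed without mock replicate 1 of hybridization 3 (adjusted p = 0.0354 and 0.0419), and the full set of rising genes also without miR-125 replicate 3 (adjusted p = 0.0276). With the 200 largest changes alone the falling genes were lower (adjusted p = 6.22e-11, and adjusted p = 0.301 with an estimated correlation) and the rising genes did not pass (adjusted p = 0.0672). In the direct contrast none of the 4 sets passed (adjusted p = 0.785 each).

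The overlap between let-7 and miR-125 addressed whether they move the same genes. Over 9105 genes measured in both comparisons, the log2 differences correlated across genes at 0.415 and had the same sign in 65.0%. The mock arrays of replicates 2 and 3 serve both comparisons: simulated unchanged groups set against these shared arrays gave a correlation of 0.335, a shared sign in 61.0% and a covariance of 0.0204, where the real covariance was 0.0494. With the mock arrays divided so that none served both, the covariance was 0.0410 or 0.0450 and the correlation 0.268 or 0.305. These values cover the 9935 genes of the 10 arrays normalized together, another set than the 9105 above. No chance value was computed for divided mock arrays, and the simulated 0.335 holds for shared ones only. It is not stated whether the mock replicate 1 arrays of hybridizations 2 and 3 hold the same RNA. With 0 genes past the threshold after miR-125, none could pass in both comparisons, so this count says nothing about shared genes. With quantile normalization without background correction 9 genes were higher in both and 7 lower in both, with no chance value for shared mock arrays computed in that setting. Genes are not independent replicates in these correlations.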

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

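The tests of the variance prior, of the replicate block, of background correction, of mock arrays divided between the microRNAs and of other cell types were chosen after the results were seen, while those of known targets and of scaling were planned. In the mock group of 4 arrays, 9 of 51 values examined had 1 array far from the other 3. Chance gives about 1 in 20 for exchangeable arrays, which these were not: 5 of the 9 values are of the only mock array of hybridization 2, so no valid chance value was at hand. Mock replicate 1 of hybridization 2 had a mean raw signal of 1523 (756 to 858 on the others) and a signal over background of 5.89 (3.18 to 3.36), where the arrays of hybridization 2 as a whole had 1429 to 1523 and 5.89 to 5.99. The same array had a median log2 signal of 9.03 for known let-7 targets (9.23 to 9.26) and of 10.18 for known miR-125 targets (10.01 to 10.03), and a log2 signal of 6.47 for Dusp23 (7.16 to 7.28). Mock replicate 1 of hybridization 3 had a median of 8.90 for cell cycle inhibitors (9.34 to 9.42) and a log2 signal of 8.42 for Rhebl1 (8.75 to 8.81). Mock replicate 2 had a median of 6.93 for interferon response genes (6.27 to 6.32), and mock replicate 3 a log2 signal of 6.73 for Slc46a3 (7.34 to 7.43).

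Only 2 genes passed after let-7 and 0 after miR-125 (limma), although 1724 and 1842 genes had an unadjusted p under 0.05. With a variance prior that follows intensity, on unchanged values, 303 and 235 genes passed, so 1 prior shared by dim and bright genes may account for part of the low counts. The replicate block with nothing else changed gave 6 and 3 genes, but leaves 2 residual degrees of freedom in place of 3 and 4, so it decided nothing about differences between the tamoxifen treatments. These stay open, since both changes together gave 1567 and 2441 genes, the block with no background correction gave 1354 and 2297, and in the direct contrast the block raised 118 genes to 579. No biological explanation was tested.

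Cell cycle genes were lower after both microRNAs, in 41 and 40 of 42 members. Known let-7 and miR-125 targets on the list did not account for it, since the 35 other members lay at a median of -0.37 after let-7 and -0.44 after miR-125, relative to all genes, all 35 lower in each. Quantile normalization did not either, since median scaling gave -0.37 and -0.43, nor did background correction, since the values without it gave -0.33 and -0.36. With the mock arrays divided so that none served both comparisons, the medians nearer to 0 were -0.44 and -0.45, which argues against the shared mock arrays but not against a shared mock RNA: whether the replicate 1 arrays of hybridizations 2 and 3, 1 on each side, hold the same RNA is not stated. Slower division under the microRNAs stays open and was not tested, nor were differences in cell density or time of harvest. No group was given another small RNA, so changes common to both microRNAs were not separated from effects of giving any small RNA.

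Genes that rose most in the knockout included Tgfbr2, Anxa5 and Thbs2, which are also expressed outside the neural lineage. Knockout cultures made up mostly of mesenchymal cells were argued against. Of 18 named mesenchymal and smooth muscle markers, 4 (Dcn, Col5a1, Acta2 and Twist1) were above background with a higher mean, by any amount. Only Dcn and Col5a1 passed, while Col1a1, Col1a2, Col3a1, Lum and Postn were not detected on any knockout array. A small share of mesenchymal cells cannot be excluded by such counts, and Dcn was above background on 3 knockout arrays and 0 flox/delta arrays. Knockout cultures made up mostly of pluripotent cells were argued against as well. Of 19 markers, 3 (Esrrb, Klf2 and L1td1) were above background with a higher mean, by any amount. Only Klf2 passed, while Nanog and Pou5f1 were not higher. In flox/delta cells 6 of the 19 pluripotency markers were above background on all 3 arrays. A small share of pluripotent cells, or such cells in both groups, therefore cannot be excluded. Of the mesenchymal markers 1 is also on another list, and 4 of the 18 were above background in flox/delta cells. A change within the progenitors, after loss of Dgcr8 or with the tamoxifen or mock treatment, stays open and was not tested.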

How the results depend on the processing

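Chosen after the data were seen were the intensity-dependent prior, the combined settings, the offsets of 50 and 100, the lists without single arrays, and the block with the numbers of the normalized tables. The counts for differentiation and the knockout held within 1.5 times under all other settings (4405 to 5071 and 4188 to 4506 without single arrays), except for 3109 and 2723 with a fold of at least 1.5, which asks for more, and 2635 and 1397 with median scaling. The counts after let-7 (2 genes) were 251 with quantile normalization without background correction, 251 with the deposited values, 106 with median scaling, 0 with no filter, 5 with every probe on its own, 6 with the replicate block, 13 with all 10 arrays, 5 and 60 at offsets of 50 and 100, 0 with no hybridization term, 0 in hybridization 3 alone, 303 with the intensity-dependent prior, 1567 with this prior and the block, 1354 with the block and no background correction, and 0 to 0 without single arrays. Cdkn2b and Ramp2 were among the genes past in each setting with a count above 0. The counts after miR-125 (0 genes) were, in the same order of settings, 187, 186 and 44, 3 with the block, 350 with all 10 arrays, 137 at an offset of 100, 235 with the prior, 2441 with prior and block, 2297 with the block and no background correction, and 0 to 0 without single arrays. The direct count (118) was 372 with quantile normalization without background correction, 201 with median scaling, 17 with no filter, 299 at a detection p of 0.01, 579 with the block, 0 in hybridization 3 alone, 333 with the prior, 1699 with prior and block, 1604 with the block and no background correction, and 0 to 76 without single arrays. Of the 118 genes, 109 remained with no background correction and 118 with the block. The cause was not tested, beyond the larger or smaller number of arrays and genes that some settings use by construction.

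With an estimated correlation no list or set passed. The p-value rose even where the estimate lay below the preset 0.01. For ribosomal genes in differentiation the estimate was -0.018, and the unadjusted camera p went from 0.00187 to 0.0251. With an estimated correlation camera tests on the residual degrees of freedom of the fit, 3 to 6 without the replicate block. With the preset correlation it uses nearly as many as there are genes. The p-values can therefore rise without larger correlations between genes, and a list short of the threshold here is not shown to be unchanged. In differentiation the values with an estimated correlation were adjusted p = 0.335 for astrocytes and oligodendrocytes, 0.235 for neurons, 0.0883 for the cell cycle, 0.227 for p53, NF-kB and ribosomal genes, 0.444 for hypoxia and 0.361 for known let-7 targets. In the knockout they were 0.430 for astrocytes, 0.201 for oligodendrocytes and known let-7 targets, 0.212 for neurons, microRNA biogenesis and amino acid response, and 0.352 for the cell cycle. They were 0.693 for each list after let-7, 0.947 (known targets) and 0.963 (cell cycle) after miR-125, and 0.956 for both lists of the direct contrast. For the knockout sets they were 0.148 after let-7 and 0.182 after miR-125, and for the differentiation sets after let-7 0.184 and 0.182. The replicate block moved the neural progenitor list of the knockout to adjusted p = 0.0455 (adjusted p = 0.495 with an estimated correlation) and changed no other call apart from the counts above. Differentiation and knockout arrays share only a number: the block gave 5172 and 5173 genes (5355 and 5173 with the normalized tables' numbers), the correlations of same-numbered arrays were -0.01, 0.18 and -0.07, and 0.11, 0.24 and 0.08, and each array was closest to its own number in the knockout comparison only. The falling differentiation genes after let-7 gave adjusted p = 0.0547 with no filter, and after miR-125 the top 200 of them gave 6.22e-11 (adjusted p = 0.301 with an estimated correlation).

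Without single arrays, adjusted p spanned 0.0248 to 0.0510 (neurons), 0.00128 to 0.0510 (NF-kB) and 0.0252 to 0.0871 (let-7 targets) in differentiation, and 0.0333 to 0.216 (hypoxia), 0.0322 to 0.317 (imprinted), 0.0195 to 0.0472 (neural progenitors) and 0.00933 to 0.255 (neurons) in the knockout. After let-7 it spanned 0.0354 to 0.656 (immediate early), 0.000121 to 0.0511 (interferon), 0.0354 to 0.345 (microRNA biogenesis) and 0.0250 to 0.148 (falling differentiation genes). After miR-125 it spanned 0.0400 to 0.978 (amino acid), 0.0186 to 0.978 (immediate early), 0.0186 to 0.877 (p53), 0.0276 to 0.770 (rising differentiation genes) and 0.0419 to 0.770 (falling ones). In the direct contrast it spanned 0.000377 to 0.267 (interferon) and 2.97e-05 to 0.00385 (known miR-125 targets). Genes past in both microRNA comparisons numbered 9 higher and 7 lower with quantile normalization without background correction, and 334 and 331 with prior and block. Of the named genes, 1526 of 1541 values in differentiation and 1537 of 1560 in the knockout kept direction and side of the threshold, the others falling short of it, as did 194 of 393 in the direct contrast, where 197 fell short and 2 reversed (Pygl, let-7 against miR-125, -1.72 to 0.24 without single arrays, with 0.24 and 0.12 without miR-125 replicates 2 and 3). For let-7 77 of 109 did so, 18 fell short, 12 newly passed and 2 moved by more than their spread, and for miR-125 49 of 56 did so and 7 newly passed. The deposited values were not run for the direct contrast, which has no common normalization, nor seed site sets, and hybridization 2 alone is 1 array against 1, a value with no test. Signal over background, 2.22 to 3.15 in hybridization 1, limits what can be seen of dim genes.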

Other observations

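The fit with the intensity-dependent prior and the replicate block, and the genes named from it, were chosen after the results were seen. The 10 splits were planned. Wrong calls were not simulated for this fit. No gene named from it here passed in the same comparison without the block and this prior. In that fit the largest rises after let-7 included Upp1, uridine phosphorylase (2.34; 2.80, 2.60 and 1.61 in replicates 1 to 3, adjusted p = 1.17e-06), Gadd45a (1.70), Ociad2 (1.46), Qpct (1.46), Pold4 (1.34) and Cbr3 (1.33). The largest falls included the smooth muscle actin gene Acta2 (-1.73, adjusted p = 2.66e-05), Prtg (-1.0), Atxn1 (-0.99) and Ccn2 (-0.99), each largest in replicate 1. Igdcc3, the largest rise in the knockout at 6.08, fell by 0.87 (-1.84, -0.63 and -0.15 in replicates 1 to 3, adjusted p = 0.00542, and adjusted p = 0.237 without the block and this prior), and Prtg had risen by 2.59 in the knockout. Of the lists, 15 known let-7 targets fell and 1 rose, 27 cell cycle genes fell and 5 interferon response genes rose.

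After miR-125 the same fit gave rises of Egr4 (1.84), Upp1 (1.71, adjusted p = 8.26e-06), Cdkn2b (1.53, adjusted p = 3.80e-06), Acta2 (1.51), Cnn2 (1.44), Bok (1.33), Egr2 (1.28) and Phlda3 (1.22). It gave falls of Apmap (-1.27), Nrm (-1.27), Fen1 (-1.23), Clspn (-1.05), Igf2bp3 (-1.05), Trp53inp1 (-1.03, adjusted p = 8.26e-06) and Igdcc3 (-0.97). Without the block and this prior, adjusted p after miR-125 was 0.0982 for Upp1, 0.143 for Fen1, 0.183 for Acta2 and 0.282 for Igf2bp3. Igf2bp3 had risen by 1.32 in the knockout. Acta2 lay on opposite sides after the 2 microRNAs, and the direct contrast of the report missed the threshold (-2.57 ± 0.59, adjusted p = 0.0737). Of the lists, 21 known miR-125 targets fell, and 33 cell cycle genes fell and 1 rose. Genes that passed in both comparisons of this fit numbered 334 higher and 331 lower, and 96 went opposite ways. Mock replicates 2 and 3 serve both comparisons and unchanged groups were not simulated for this fit, so whether these counts exceed chance is not known.

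With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5193 genes in differentiation, 5005 in the knockout, 2 for let-7 and 118 in the direct contrast. The highest other split gave 0 in each, and 1 of 10 splits, the real one, reached the count. Every other split mixes the groups, so a real difference widens its spread and makes a count of 0 likely. These counts of 0 therefore lend the real counts no support. For miR-125 all 10 of 10 splits gave 0. The let-7 median of known targets lay 0.557 below all genes, where the highest other split gave 0.362. Among the 4 splits that part as many pairs, the real one included, the highest other gave 0.302. The miR-125 median of known targets lay 0.474 below (0.261 in both). The knockout sets lay 0.267 apart after let-7 (0.234, and 0.166 among other splits parting as many pairs) and 0.221 apart after miR-125. For the latter 2 of 10 splits were as large. Mock replicate 1 with miR-125 replicates 1 and 2 against the rest gave 0.236, a split that keeps replicate 1 together. Of the 4 splits parting as many pairs, the real one included, the highest other gave 0.110. For all others but the miR-125 count, 1 of 10 splits reached the value.

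The undifferentiated flox/delta columns numbered 1 and 3 in the normalized tables had the ranks of the raw columns with the other number (rank correlation 1, and 0.916 with their own number), and the same held for the knockout columns (0.909). The mock arrays of replicate 1 in hybridizations 2 and 3 correlated across probes at 0.902, within the 0.897 to 0.928 of arrays of 1 group and hybridization.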
